A study of Homo sapiens with 2 samples.

How the data were processed

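RNA from A673 cells was sequenced as poly(A)-selected libraries after transduction with lentivirus for a RUNX3 hairpin or a non-target hairpin. Per the labels' protocols, virus made in HEK 293T cells was collected after 72 hours, applied with 6 µg/mL polybrene, and transduced cells were selected with 0.4 µg/mL puromycin for 6 days. The titles name each library as a pool, and each group has 1 library. The sample titles and the shRNA characteristics disagree for both libraries. Groups were taken from the titles before the data were examined, the RUNX3 level was reported and moved no library, and the libraries are called by their titles.

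The authors deposited a gene table and an exon table for each library. Per the submitters' processing notes the reads were handled with CASAVA 1.9, TopHat2 2.0.6 and HTSeq on genome build hg19; the notes as used here give no role or order, and the gene annotation, strand setting and filters are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart. Per the file headers the tables hold raw counts per gene and per exon, and RPKM values per gene and per exon. The authors' RPKM is the count scaled to gene length and to a total number of reads; recomputing it showed totals of 60848394 reads for the library titled 813 and 63156235 for the library titled NT, more than the gene counts sum to. The deposited gene counts are all even numbers (0 odd values in either library) while 36.4% and 35.5% of the exon counts are odd, so a gene count was read as 2 reads per counted pair and divided by 2. The design fixed beforehand was written for counts as deposited; scaling and folds are the same either way, and the intervals from undivided counts were run as an alternative.

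The 23398 gene rows held 46 repeated rows, which were dropped, leaving 23352 genes; 28 of them had a date in place of a gene symbol and were kept as listed. The exon tables held 230470 records. Gene counts summed to 46936662 and 48921868 as deposited, or 23342660 and 24326135 pairs counted over the genes kept. Library sizes were scaled by TMM (edgeR 4.0.16 in R 4.3.3), with factors of 1.05 for the library titled 813 and 0.954 for the library titled NT, giving 24461352 and 23213627 effective pairs. The log2 fold is the ratio of pairs scaled to these effective sizes with a prior of 0.5 pairs, the library titled 813 over the library titled NT. Its interval is the exact 95% conditional binomial (Clopper-Pearson) interval of the 2 counts, computed with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15. It covers counting error only, since PCR copies are not independent molecules and 1 library per group shows no spread between cultures. A gene was measured at 1 CPM or more in at least 1 library, and called higher or lower at 2-fold or more with the interval wholly beyond 1.5-fold. No p-value was computed across genes. A gene with 0 pairs in 1 library is given as a bound against a floor of 3 pairs.

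Before use the rule was tested on simulated counts drawn from the means and sizes of these 2 libraries, with 200 genes changed. Equal numbers of genes were raised and lowered and the true library sizes were given, so the scaling by TMM was not tested. With counting noise alone, 3 unchanged genes of 12132 run were called, and 0% of genes changed 1.5-fold, 88% changed 2.5-fold, 98% changed 4-fold and 100% changed 8-fold were recovered. With an assumed biological coefficient of variation of 0.1, 0.2 or 0.3 the unchanged genes called were 6, 227 and 1264, so the counts of calls depend on a spread between cultures that these data do not give. Of 400 simulated random lists of 20 unchanged genes, 5.0% fell outside the central 95%. The genes of these lists were simulated independently, so this checks the calculation only and not lists whose genes vary together.

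The 34 gene lists, fixed before the data were examined, were each described by the median log2 fold of their measured genes and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins; a list stood apart under percentile 2.5 or over 97.5. The rule for named genes, fixed at the same time, took RUNX1, RUNX2, RUNX3, CBFB, EWSR1 and FLI1, the 12 higher and 12 lower genes whose interval bound nearest to no difference lay farthest from it, and up to 4 called members in each direction from each list that stood apart or had at least 2 called members. It also took up to 5 exons with the largest departures. Some genes that the rule names are not reported here. Genes that shared 50% or more of their transcript at 97% identity or more with another gene (blastn 2.17.0 on GENCODE release 29) were to be left out, and none was. FLI1 exon counts were split before exon 6, and exon numbers follow the exon lengths of the reference transcript. Exon reads are given as deposited. For exon folds, intervals and densities they were divided by 2, since both reads of a pair can fall in an exon. An exon departed from its gene when its fold and that of the other exons differed 2-fold or more with intervals that did not overlap. Coordinates are those of the deposited tables in hg19; the reference, on GRCh38, was used for GC content, strand and sequence only, and 92.6% of the genes matched it by name.

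Alternatives were plain total counts, DESeq2 1.42.0 size factors, a prior of 5, exon sums, the authors' RPKM on the log2(RPKM + 0.05) scale, library sizes without the 20 most abundant genes, other CPM filters and thresholds, random lists matched on length as well, and other splits and read minimums for exons. Added after seeing the data were the removal of a smooth trend on GC content and gene length (mgcv 1.9.3; 11838 genes, 96.6% of those measured), intervals from undivided counts, a count without genes overlapped by other genes over 20% or more of their exons, and an excess of FLI1 exons with unfused FLI1 2 times denser over exons 6 to 9.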

Results

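The series compared A673 cells carrying a short hairpin RNA against RUNX3, a Runt-domain transcription factor, with A673 cells carrying a non-target hairpin. A673 is an established human Ewing sarcoma line in which the 5' part of EWSR1 is joined to the 3' part of FLI1, and the fusion protein EWS/FLI1 acts as the tumour's driving transcription factor. Poly(A) RNA was sequenced from 1 library per group, so no difference has a replicate check and none was tested. The title and the shRNA characteristic of each library contradict each other. The libraries are therefore named by their titles, 813 (the name of the RUNX3 hairpin) and NT (non-target), and taking the characteristic in place of the title turns every direction round. Gene counts summed to 23342660 read pairs in the library titled 813 and 24326135 in the library titled NT, with at least 1 pair in 17306 and 16910 genes. The 20 most abundant genes held 9.90% and 10.3% of the pairs. Intervals are exact 95% binomial intervals and cover counting error only.

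RUNX3 (chr1:25226002-25291501 in hg19, minus strand) was the targeted gene and is given first as a check of the labels. It had 387 pairs (15.8 CPM, pairs scaled to the effective library size) in the library titled 813 and 1391 pairs (59.9 CPM) in the library titled NT. The log2 fold was -1.92 (-2.09 to -1.76), a level 3.79-fold lower in the library titled 813. This goes with the titles and against the shRNA characteristics. Each RUNX3 exon record with reads in both libraries was lower in the library titled 813, with log2 folds from -1.82 at the 3' exon (chr1:25226002-25229157, 647 and 2173 reads) to -2.76 at chr1:25254065-25254221 (27 and 179 reads). The 5'-most record (chr1:25291005-25291501) had 0 and 2 reads, so transcripts from the distal start were near the limit of detection in both libraries. Among the partners of RUNX3, CBFB, the shared non-DNA-binding subunit of the RUNX factors, was higher in the library titled 813 with 698 and 271 pairs and a log2 fold of 1.29 (1.09 to 1.497). RUNX2 had 53 and 24 pairs, a log2 fold of 1.05 (0.35 to 1.83) that did not pass the rule of size. RUNX1 had 4 and 1 pairs and lay under 1 CPM in both libraries.

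EWSR1 and FLI1 were examined by exon because the fusion uses only part of each gene. EWSR1 (chr22:29663998-29696515) had a log2 fold of -0.18 (-0.22 to -0.13) for the gene, -0.09 (-0.17 to -0.02) over its first 7 exon records and -0.19 (-0.24 to -0.14) over the others. These 7 records include an 18-base record (chr22:29670254-29670271) and were not matched to the exon numbers of a transcript. The split therefore need not fall at the fusion point. FLI1 (chr11:128563811-128683162) was not uniform along its length. Exons 6 to 9, which lie 3' of the usual fusion point, had 1887 reads in the library titled 813 and 1230 in the library titled NT, a ratio of 1.46 (1.31 to 1.61). Exons 1 to 5 had 183 and 28 reads, a ratio of 6.03 (3.51 to 11.8). The share of FLI1 reads in exons 1 to 5 was 8.84% (Clopper-Pearson 7.18 to 10.7) in the library titled 813 and 2.23% (1.22 to 3.71) in the library titled NT. Exons 2, 3 and 4 had 45, 40 and 51 reads in the library titled 813 against 5, 4 and 8 in the library titled NT. Read density was higher over exons 6 to 9 than over exons 2 to 5 in both libraries, at 12.9 against 4.78 CPM per kb in the library titled 813 and 8.88 against 0.710 in the library titled NT. The excess of exons 6 to 9 over exons 2 to 5 was 8.15 and 8.17 CPM per kb, with a ratio of 0.997 (0.809 to 1.20). This takes unfused FLI1 as equally dense over both parts, which was not measured. With unfused FLI1 taken as 2 times denser over exons 6 to 9, the ratio was 0.45 (0.117 to 0.771), and a sparser profile was not tried. Over the whole gene FLI1 had a log2 fold of 0.61 (0.46 to 0.76), below the rule of size.

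**Figure D1:**
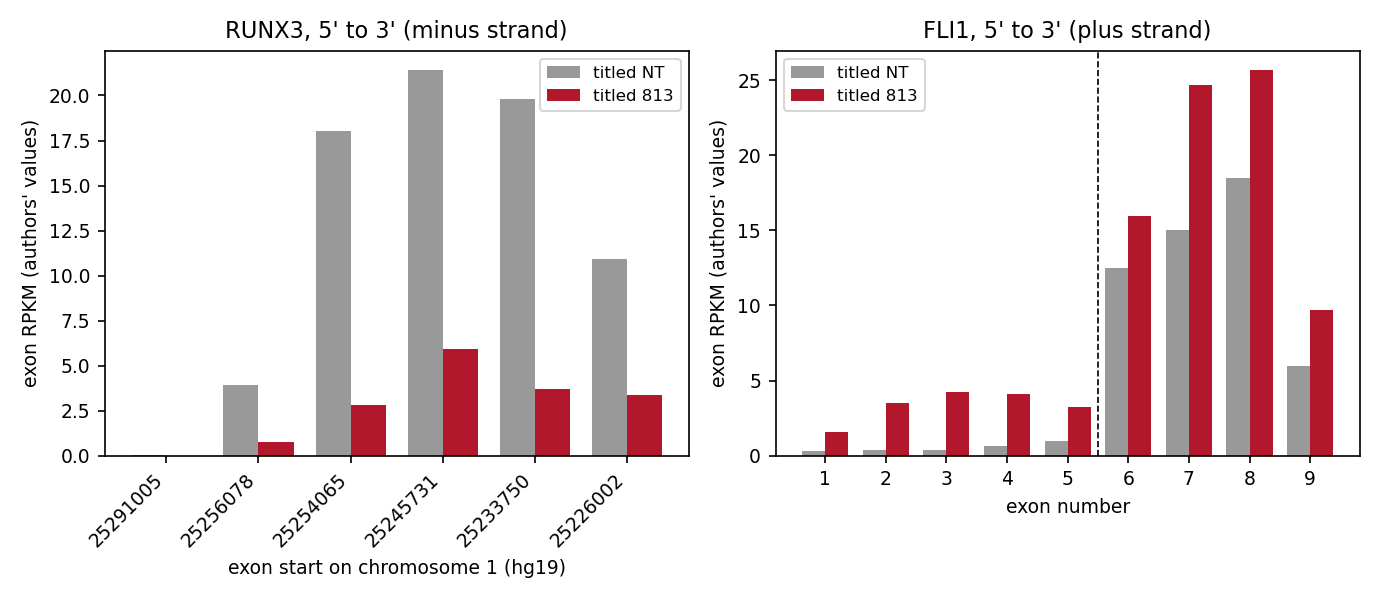
Exon expression of RUNX3 (left) and FLI1 (right) in the authors' RPKM (vertical axes from 0), with grey bars for the library titled NT, red bars for the library titled 813, exons in transcript order, and a dashed line between FLI1 exons 5 and 6; with 1 library per group the bars have no error bars. RUNX3 was lower in the library titled 813 at each exon with visible signal, and FLI1 exons 1 to 5 were near the base line in the library titled NT and higher in the library titled 813.

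Of 12254 genes with 1 CPM or more in at least 1 library, 996 were higher and 427 lower in the library titled 813 by the rule of size (2-fold or more, with the interval wholly beyond 1.5-fold), and 10831 passed in neither direction. Differences of 4-fold or more were seen in 166 of the higher and 55 of the lower genes. Higher genes made up 70.0% of the calls with TMM scaling, 81.5% with plain total counts (1330 higher, 302 lower) and 79.7% with the authors' RPKM (1339 higher, 341 lower). Plain totals moved log2 folds up by 0.14 relative to TMM, less for genes with few pairs, and the directions given here are relative to TMM. A smooth trend on GC content and gene length explained 15.6% of the variance of the log2 fold, and its removal left 709 higher and 291 lower genes, 584 and 250 of them shared with the counts above.

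The 12 genes most clearly higher in the library titled 813 included secreted proteins and cytokines. MMP1, an interstitial collagenase, had 468 and 21.5 CPM, a log2 fold of 4.44 (4.32 to 4.58). IL1B, an inflammatory cytokine, had 4.99 and 0.215 CPM (log2 fold 4.41, 3.27 to 6.18). Its chromosome 2 neighbour IL1A had 32 pairs against 0, at least 10.1-fold higher against a floor of 3 pairs; the counting interval of its log2 fold, which uses the 0 pairs, starts lower, at 2.96. NT5E, the cell surface enzyme CD73, had 24.98 and 1.46 CPM (4.07, 3.59 to 4.64). DKK3, a secreted glycoprotein of the Dickkopf family, had 34.0 and 2.15 CPM (3.97, 3.57 to 4.42). F2RL2, a protease-activated receptor, had 22.2 and 1.895 CPM (3.54, 3.11 to 4.03). FAIM2, which inhibits Fas-mediated death, had 15.5 and 0.431 CPM (5.10, 4.27 to 6.24), and UBE2QL1 had 26.1 and 2.84 CPM (3.19, 2.83 to 3.59). C2CD4A, MTUS2, LRRC55 and SLCO2B1 completed the set with 139, 51, 48 and 65 pairs in the library titled 813 and 3, 1, 1 and 3 pairs in the library titled NT. Their log2 folds were 5.25 (3.88 to 7.75), 5.04 (3.05 to 10.9), 4.95 (2.96 to 10.8) and 4.16 (2.75 to 6.68).

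The 12 genes most clearly lower included a lineage transcription factor and epithelial sodium channel subunits. PAX7, a paired-box factor of neural crest and muscle progenitors, had 856 and 4433 pairs (35.0 and 191 CPM), a log2 fold of -2.45 (-2.56 to -2.34). SCNN1G and SCNN1B, subunits of the epithelial sodium channel, were lower with log2 folds of -2.35 (-2.44 to -2.26) and -2.63 (-2.84 to -2.43). PADI2, a peptidylarginine deiminase, had 46.0 and 305 CPM (-2.73, -2.82 to -2.64), and CHST1, a carbohydrate sulfotransferase, 11.3 and 76.6 CPM (-2.76, -2.95 to -2.57). CAMSAP3, which binds microtubule minus ends, had 2.49 and 24.9 CPM (-3.31, -3.73 to -2.94). MS4A1, the B-cell surface protein CD20, had 1 and 87 pairs, a log2 fold of -5.93 (-11.8 to -4.00). RASAL1, a Ras GTPase-activating protein, had 1 and 52 pairs (-5.19, -11.1 to -3.23). GPR123, GNG7, CUX2 and UNC5A had log2 folds of -2.95, -2.80, -2.62 and -2.52.

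**Figure D2:**
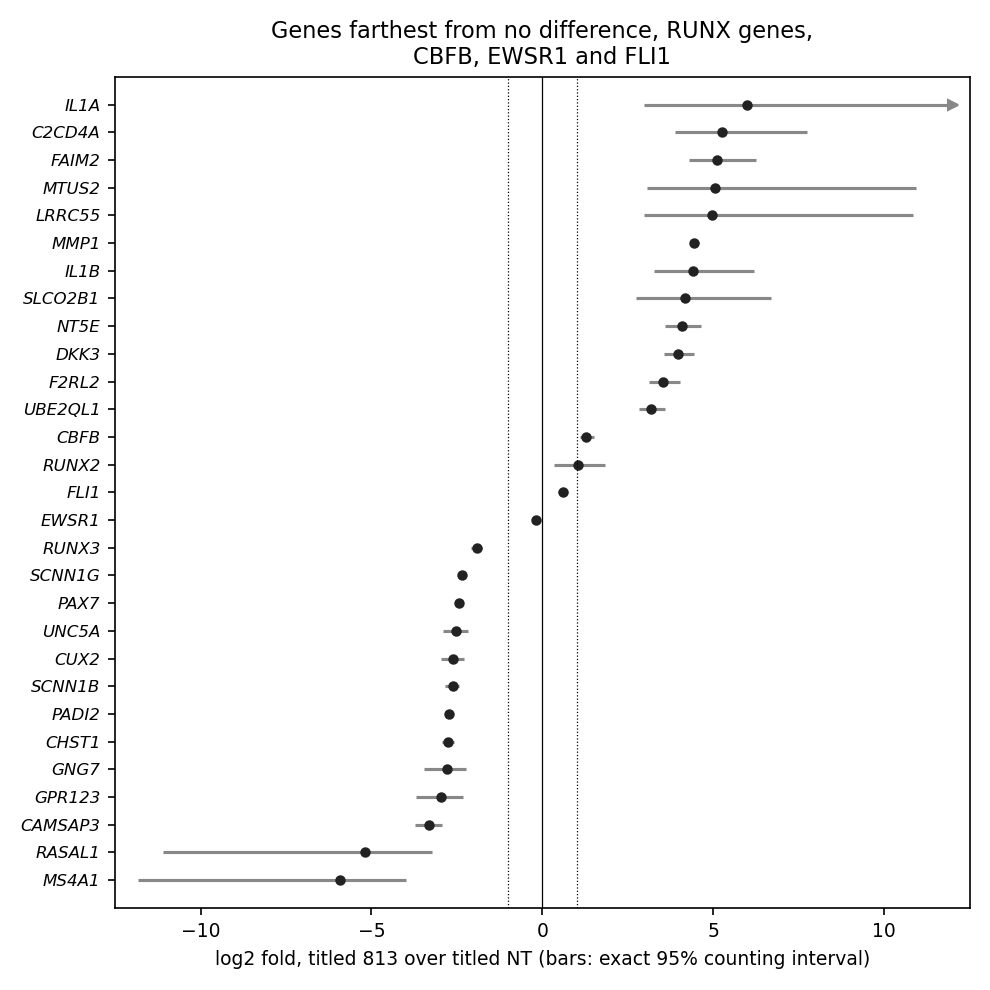
Log2 fold (horizontal axis, library titled 813 over library titled NT) of the 12 genes most clearly higher, the 12 most clearly lower, RUNX3, RUNX2, CBFB, EWSR1 and FLI1, with points for the fold and bars for the exact 95% counting interval; dotted lines mark 2-fold and the arrow an interval with no upper bound. IL1A, with 0 pairs in the library titled NT, and MS4A1, with 1 pair in the library titled 813, have wide intervals, and MMP1 a narrow one.

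The gene lists fixed before the data were examined were compared with random lists of the same size matched on mean expression. Of 32 lists with at least 3 measured genes, 11 had a median above and 3 a median under the central 95% of 10000 random lists. Random lists draw genes singly, so they do not show how far genes that vary together would move between any 2 cultures. Among 28 genes described as repressed by EWS/FLI1, 26 were measured and 12 were higher and 0 lower in the library titled 813, with a median log2 fold of 0.94 at percentile 100. They included DKK1, a secreted Wnt antagonist (log2 fold 3.18, 2.15 to 4.63), TGFBI (2.19, 2.16 to 2.23), TNC (2.15, 2.12 to 2.18) and TGFBR2, the type II TGF-beta receptor (2.04, 1.83 to 2.26). Among 38 genes described as activated by EWS/FLI1, 5 were lower and 2 higher. The lower ones were PPP1R1A (-1.49), the transcription factor NKX2-2 (-1.43), TERT (-1.27), LBH (-1.24) and the nuclear receptor NR0B1 (-1.11), and the higher ones were GPR64 (1.30) and E2F3 (1.28). The median of this list was 0.17 (percentile 99.45), opposite in sign to most of its calls, and it was -0.028 (percentile 25.6) once the trend on GC content and gene length was removed. The call of NR0B1 ended with plain total counts (-0.97) and with the trend removed (-0.73), and that of E2F3 with the trend removed (0.90).

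Extracellular matrix and adhesion genes also lay above their random lists. Of 26 measured matrix genes, 13 were higher and 1, ELN, was lower (median 0.99, percentile 100). Besides MMP1, the fibrillar collagen COL3A1 had 395 and 70.5 CPM (log2 fold 2.49, 2.41 to 2.56), the collagen cross-linking enzyme LOXL2 73.9 and 15.3 CPM (2.27, 2.11 to 2.44) and the proteoglycan BGN 723 and 162 CPM (2.16, 2.11 to 2.21). ELN, elastin, had a log2 fold of -1.03, and its call ended with plain total counts (-0.89). Of 18 measured integrin, cadherin and other adhesion genes, 8 were higher and 1 lower (median 0.77, percentile 100). The hyaluronan receptor CD44 (2.71, 2.24 to 3.24), the integrin subunit ITGA3 (2.21, 1.83 to 2.62), NCAM1 (2.07, 1.59 to 2.60) and N-cadherin CDH2 (1.68, 1.51 to 1.85) were higher, and CDH4 was lower (-1.12, and -0.99 with plain total counts, which ended its call). Among 17 mesenchymal and actin genes, 2 were higher, NT5E and the zinc-finger factor SNAI2 (2.34, 1.48 to 3.41), with a median of 0.39 (percentile 99.85). The fibroblast markers did not stand apart (5 measured, median 0.24, percentile 61.2), and neither did the endothelial markers (3 measured, median 0.55, percentile 63.8).

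Some signalling and stress lists also lay above the random lists, while others, given further on, did not stand apart. Of 22 immediate early and AP-1 genes, 9 were higher and 0 lower (median 0.89, percentile 100), among them the MAP kinase feedback genes SPRY2 (1.995, 1.63 to 2.39), SPRY4 (1.94, 1.75 to 2.13) and DUSP5 (1.51, 1.38 to 1.65) and the ETS factor ETV4 (1.67, 1.36 to 1.996). FOS and JUN themselves had log2 folds of -0.61 and 0.19. Of 11 NF-kB and inflammation genes, 4 were higher (median 0.78, percentile 98.2): IL1A, IL1B, the ubiquitin-editing enzyme TNFAIP3 (2.36, 1.97 to 2.79) and ICAM1 (1.70, 1.21 to 2.23). Among genes with 5 CPM or more this list fell back among the random lists (0.63, percentile 96.4). Of 18 apoptosis genes, 5 were higher and 0 lower (median 0.41, percentile 98.9), including the anti-apoptotic MCL1 (1.49) and BCL2 (1.34) and the inhibitor XIAP (1.35), and this list too fell back among genes with 5 CPM or more (0.33, percentile 97.2). The calls of BCL2 (0.93) and XIAP (0.99) ended with the trend on GC content and gene length removed. Of 24 interferon-stimulated genes, OASL (2.42), IFIT3 (1.89) and BST2 (1.49) were higher and OAS1 (-1.17) was lower, with a median of 0.31 (percentile 98.0, and 97.48 when the 20 most abundant genes were left out of the library size, which put it back among the random lists). Antigen presentation genes had a median of 0.50 (9 measured, percentile 99.8) with 1 gene, HLA-B (1.76, 1.66 to 1.86), called. Unfolded protein and stress response genes had a median of 0.33 (18 measured, percentile 99.95) with 1 gene, the endoplasmic reticulum chaperone HSP90B1 (1.69, 1.60 to 1.78), called.

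The lists on the lower side were neural, cholesterol synthesis and HEK293 genes. Of 15 neural genes, 2 were lower, PAX7 and the synaptic vesicle protein SYP (-1.48, -1.67 to -1.29), while GAP43 (2.41), NES (1.87) and CHGA (1.61) were higher. The median of this list was -0.43 (percentile 0.17), and -0.084 (percentile 16.1) with the trend on GC content and gene length removed, which put it among the random lists. Of 20 cholesterol synthesis and uptake genes, 3 were lower and 0 higher by the rule of size (median -0.40, percentile 0.21), while 9 had log2 folds above 0. The 3 lower genes included MVD, mevalonate diphosphate decarboxylase (-1.52, -1.58 to -1.45), and FDPS, farnesyl diphosphate synthase (-1.003, -1.04 to -0.97). The call of FDPS ended with plain total counts (-0.87). The 5 measured genes described as high in HEK293, the line used to make virus, had a median of -0.81 (percentile 0.27), with GATA3 lower (-1.56) and the list sharing NEFL (-0.81) with the neural list. Among genes with 5 CPM or more the HEK293 list was within its random lists (-0.43, percentile 6.96).

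The remaining lists did not stand apart. Cell cycle genes had a median of -0.26 (31 measured, percentile 5.49) with 1 lower gene, CDK1 (-1.22), chosen here after its value was seen; with the trend on GC content and gene length removed the list median was -0.25 at percentile 0.12, below the random lists. Growth arrest genes had a median of 0.34 (14 measured, percentile 90.2), TGF-beta and BMP targets 0.33 (15 measured, percentile 93.1), Wnt targets -0.19 (6 measured, percentile 9.84), Notch and Hedgehog genes -0.21 (17 measured, percentile 8.45) and the insulin-like growth factor genes 0.20 (14 measured, percentile 91.2). Of the TGF-beta and BMP targets, 5 were higher, among them ID1 (1.49, 1.31 to 1.68) and ID3 (1.26, 1.20 to 1.31). Among Notch and Hedgehog genes HEY1 (2.77, 2.14 to 3.53) was higher and DTX1 (-2.43), BOC (-2.34) and NRARP (-1.54) were lower. RUNX factors and cofactors had a median of 0.22 (13 measured, percentile 86.5), bone and cartilage genes 0.09 (8 measured, percentile 89.6), with SPARC higher (1.79, 1.75 to 1.84), and HOX genes -0.01 (12 measured, percentile 37.4). Hypoxia and glycolysis genes (-0.15, 22 measured, percentile 26.7), heat shock genes (-0.17, 14 measured, percentile 40.5) and RNA interference genes (-0.07, 13 measured, percentile 39.9) were within the range of their random lists. So were ribosomal proteins (-0.27, 32 measured, percentile 17.4), housekeeping genes (-0.18, 14 measured, percentile 43.1), histones (0.10, 7 measured, percentile 40.8) and leukocyte markers (0.38, 4 measured, percentile 52.6). The epithelial list had 2 measured genes and no percentile, and the 13 mitochondrially encoded genes of the quality list were not analysed here.

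**Figure D3:**
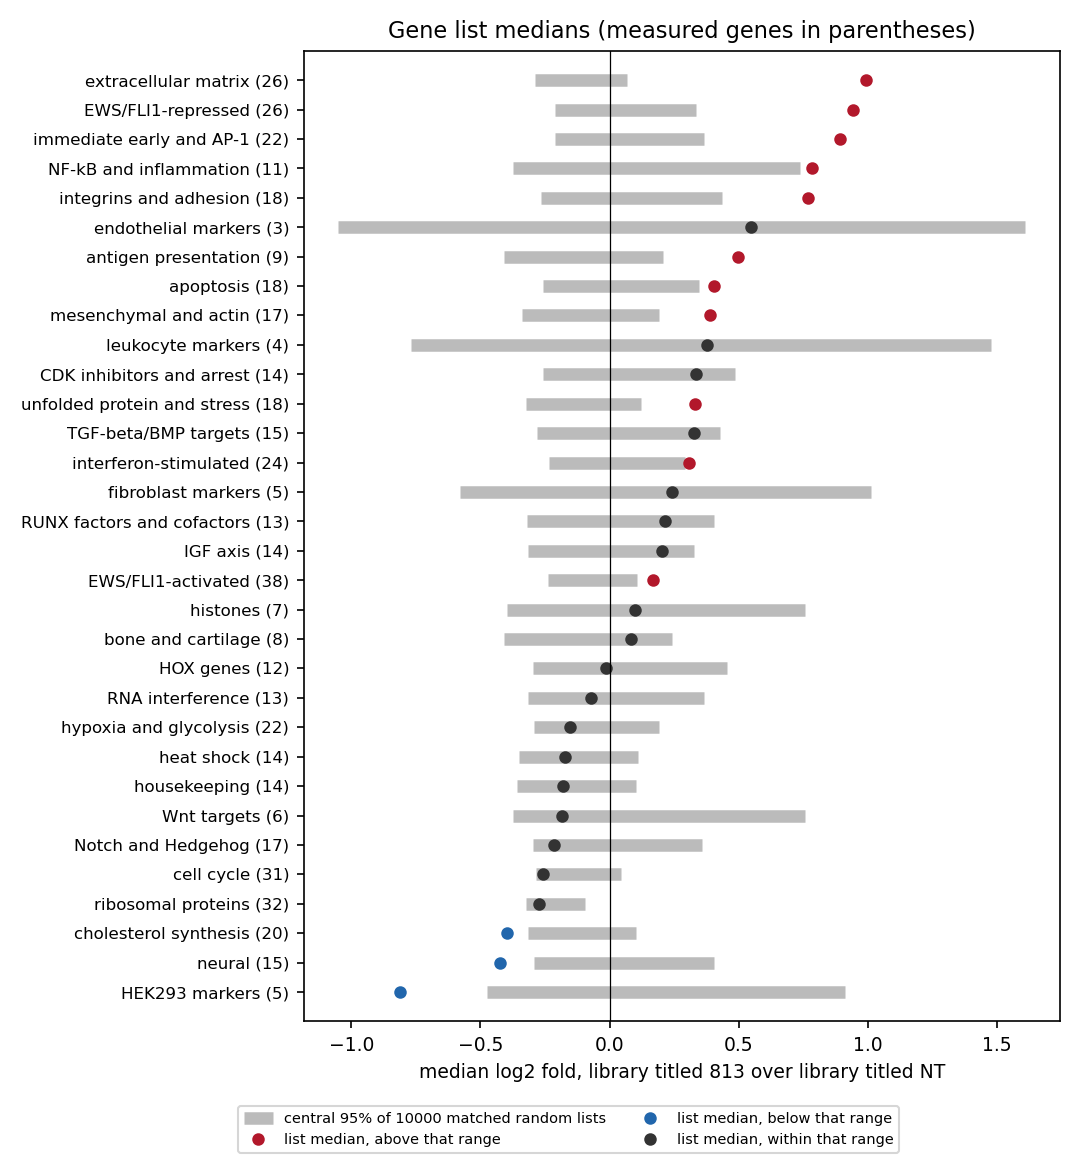
Median log2 fold (horizontal axis, library titled 813 over library titled NT) of the 32 gene lists with at least 3 measured genes, as points over grey bars for the central 95% of 10000 random lists matched on mean expression; red points lie above, blue points under and black points within that range. The EWS/FLI1-repressed and extracellular matrix lists, at 0.94 and 0.99, lie farthest to the right of their bars.

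Exons that departed from the rest of their gene were sought among 91162 exons with at least 50 reads in genes with at least 200. Of these, 371 exons (0.407%) in 258 genes differed 2-fold or more from the other exons of their gene with intervals that did not overlap, 192 upward and 179 downward in the library titled 813. The 5 largest departures lay in 3 genes. In UGT3A1, a glycosyltransferase gene, the exons chr5:35988552-35988653 and chr5:35968121-35968235 had 1775 and 1774 reads in the library titled 813 against 3 and 6 in the library titled NT, although the whole gene had 12 and 36 pairs. In GSTM2, a glutathione transferase gene, chr1:110224431-110224456 had 2 reads in the library titled 813 and 418 in the library titled NT, while the gene as a whole had a log2 fold of -0.90. In LOC100130015, chr16:90114151-90114191 and chr16:90113946-90114033 each had 117 and 2 reads.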

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

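The trend on GC content and gene length, the intervals from undivided counts, the count without overlapping genes and the denser profile of unfused FLI1 were chosen after seeing the data. No paired analysis was possible because each group has 1 library. RUNX3 was lower in the library titled 813 under each scaling tried and turned round to 1.92 when the shRNA characteristic set the groups, which swaps the libraries by construction.

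Counts of calls followed the thresholds, with 2429 higher and 1370 lower genes at 1.5-fold with the interval beyond 1, and 158 and 53 at 4-fold with the interval beyond 2-fold. Undivided counts gave 1120 and 495, DESeq2 size factors 967 and 439, exon sums 1040 and 437, and the count without overlapping genes 978 and 416. Exon sums gave the opposite call for 1 gene, and the other alternatives for 0.

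Of the lists that stood apart, 4 returned to the random range under an alternative fixed beforehand. These were the interferon list (0.31) without the 20 most abundant genes, and apoptosis (0.33), NF-kB and inflammation (0.63) and HEK293 genes (-0.43) among genes with 5 CPM or more, where fewer members were measured. With the trend on GC content and gene length removed, the EWS/FLI1-activated list reversed to -0.028 and the neural list weakened to -0.084, while the cell cycle list moved below the random range at -0.25; among genes with 5 CPM or more the TGF-beta and BMP targets moved above it at 0.58; the cause was not tested beyond the removal itself. Of 98 named genes besides RUNX3, the call or its absence was kept in 91 with total counts, 91 with the authors' RPKM, 96 with a prior of 5 and 85 with the trend removed, and in all 98 with DESeq2 size factors, exon sums or without the 20 most abundant genes.

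Splitting FLI1 before exon 7 put 11.9% of its reads upstream in the library titled 813 and 6.36% in the library titled NT, since exon 6 then counts as upstream. Unfused FLI1 taken as 2 times denser over exons 6 to 9 moved the ratio of the excess from 0.997 to 0.45. Exons departing from their gene numbered 232 with 100 reads per exon and 500 per gene, and 106 at 3-fold. Depth limits genes under about 1 CPM, such as RUNX1 with 4 and 1 pairs.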

Other observations

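The tests on GC content and gene length and on olfactory receptor genes were set before their results were seen; the neighbour, family and B-cell values and the tests on fibroblast, fusion, endothelial or leukocyte RNA, alignment gaps and overlapping genes were chosen after.

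Genes called the same way lay next to each other more often than shuffled calls. Among 8294 pairs of neighbouring measured genes within 100 kb, with records that do not overlap, 104 pairs were called in the same direction, against a mean of 61.4 (central 95% 48.0 to 76) over 1000 shuffles of the calls within bins of mean expression. Pairs called in opposite directions numbered 26, against 44.3 (32 to 58). With the trend on GC content and gene length removed, the same-direction pairs were 57, against 31.4 (22 to 43), and the opposite pairs 15, within the shuffled range (mean 22.6, 14 to 32). Examples are IL1A with IL1B and F2RL2 with its fellow protease-activated receptor genes F2R (log2 fold 2.39) and F2RL1 (3.10), all higher in the library titled 813. COL3A1 with COL5A2 (1.56), MMP10 (1.45) with MMP1, and LRRC55 with the apelin receptor gene APLNR (3.50) were higher too. SCNN1G with SCNN1B and DTX1 (-2.43) with RASAL1 were lower. Pairs were not filtered for shared sequence, and the 104 include genes of the same symbol stem such as AKR1C1 with AKR1C2 and GOLGA8A with GOLGA8B. They also include PDE1B with PPP1R1A, whose records adjoin and which share 14.8% of the PPP1R1A transcript. Reads shared between such neighbours could raise the number of same-direction pairs.

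Of 193 groups of genes that share a symbol stem, 9 had medians above and 7 below the central 95% of matched random lists. By chance 4.83 would be expected on each side. Some stems, such as S and TM, both among the 9 above, need not name 1 gene family. The families named here were picked after their values were seen. The collagens, without COL4A3BP, which shares the stem only, had 11 higher and 2 lower genes of 26 (median 0.43, percentile 99.85). COL1A2 had 2628 and 2180 CPM and COL1A1 163 and 202 CPM, and neither was called, while COL3A1, COL5A1 (1.67) and COL16A1 (2.20) were higher. The matrix metalloproteinase stem had 5 higher genes of 12 (median 0.95, percentile 99.99), and the SMAD stem a median of 0.74 (percentile 98.9) with 0 called genes of 8. The aldehyde dehydrogenase stem had 3 lower genes and 1 higher of 14 (median -0.47, percentile 0.16). B-cell genes were detected without the leukocyte gene PTPRC, which had 0 and 1 pairs. CD79A had 90.0 and 129 CPM, CD79B 29.8 and 9.91 CPM (log2 fold 1.58, 1.37 to 1.81) and MS4A1 0.0409 and 3.75 CPM, so these 3 genes did not move together.

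The higher level of EWS/FLI1-repressed and extracellular matrix genes in the library titled 813 was weighed against 3 explanations. With the trend on GC content and gene length removed, the EWS/FLI1-repressed median was 1.02 and the matrix median 0.75, both at percentile 100, so that trend is not the whole cause. The fibroblast genes DCN, LUM, POSTN and FAP together had 206 and 243 pairs, a ratio of 0.805 (0.665 to 0.973), which argues against RNA of fibroblasts that hold these genes. The sum was mostly DCN (124 and 146 pairs), and LUM was not lower (33 and 23 pairs). These genes were chosen after the data were seen. The fibroblast list fixed beforehand had 1 higher and 0 lower of 5 measured genes, with a median of 0.24 (percentile 61.2). PDGFRB (log2 fold 0.89) and THY1 (0.31) lay above 0 without being called. The excess of FLI1 exons 6 to 9 over exons 2 to 5 had a ratio of 0.997 (0.809 to 1.20) with unfused FLI1 taken as equally dense over both parts and 0.45 (0.117 to 0.771) with it taken as 2 times denser over exons 6 to 9. The profile of unfused FLI1 was not measured, so less of the fusion transcript stays open, and the fusion protein was not measured. Only a denser profile was tried and not a sparser one, although exon 9 had a lower RPKM (9.70 and 6.00) than each of exons 6 to 8 in both libraries. The lower RUNX3 level, a chance difference between the 2 cultures and other targets of the hairpin also stay open as untested, and need further libraries.

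The higher level of FLI1 exons 1 to 5 in the library titled 813 was weighed in the same way. RNA of endothelial cells would bring VWF, CDH5 and PECAM1, and RNA of leukocytes PTPRC, which those cells hold in abundance. Exons 2 to 5 gained 4.07 CPM per kb, and of the endothelial list with ERG, CD34 and PTPRC (11 genes) the densest in the library titled 813, EMCN (86 and 59 pairs), reached 0.214 of that gain. PECAM1 (28 and 18 pairs) reached 0.0631 of it, VWF (5 and 8) 0.00568, CDH5 (2 and 8) 0.00487 and PTPRC (0 and 1) none, which argues against both kinds of cell, although KDR was higher (52 and 5 pairs). These shares set unlike measures side by side, gene pairs over the whole gene length for the markers and halved exon reads for the gain. If reads that span exons were counted in each of them, the gain would be too large and the shares too small. The 393 olfactory receptor genes summed to 73 and 64 pairs, a ratio of 1.08 (0.763 to 1.54), which argues against more genomic DNA; unspliced FLI1 RNA was not tested and stays open. Reads that skip exons would give the exon records of this stretch nearly equal counts. The largest had 51 reads in the library titled 813 and the least 9, a ratio of 0.176; the least was an unnumbered 54-base record (chr11:128618132-128618185), and among exons 1 to 5 themselves the least had 13, a ratio of 0.255. Exons 1 to 5 lie outside the part of FLI1 that the usual fusion holds. If these cells carry that fusion point, which was not measured here, the reads would come from other FLI1 RNA. Whether such RNA starts from the intact allele or from a reciprocal fusion was not tested.

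Exons that depart from their gene may partly come from how exons were counted. In the library titled 813, 5 of the 10 UGT3A1 exon records had between 1774 and 1776 reads, in a gene with 12 pairs, next to UGT3A2 with 38586 pairs, as would be seen if spliced reads were counted on exons inside their alignment gap. Of the 371 departing exons, 40 (10.8%) held more reads than the whole gene count, against 1.02% of the 90791 other exons looked at, so this could account for a part of them; reads dropped from gene counts as ambiguous would look alike. Overlap with an exon of another gene covered 49 of the departing exons (13.2%). This does not settle the part of overlap, since an exon can also depart because the exons it is compared with are shared. In DOC2A, chr16:30016835-30017652 (1480 and 1632 reads) lay on an exon of INO80E. It was among the other exons against which chr16:30021282-30021556 (9 and 90 reads) departed. For the other departing exons no explanation was tested.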
